A study of Arabidopsis thaliana with 9 samples.

How the data were processed

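Leaf RNA of Arabidopsis thaliana was profiled on 9 one-colour arrays, 3 each from wild-type Col0 plants and from the transgenic lines P57 and P26. The series text calls these lines PG57 and PG26 and states that they overexpress AtPrx71, a class III peroxidase. Plants were grown in soil under long days, and polyA RNA was amplified and labelled with Cy5 by a kit for CombiMatrix arrays, per the labels' protocols. Nothing in the labels states that replicates came from separate plants or pools, so the p-values measure the spread between these samples, which may be technical.

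Each array's file holds 1 column of spot intensity on a linear scale, as the authors deposited it, with no separate background column and no scan date or slide. Each file lists 27763 Arabidopsis probes of 34 to 41 bases and 126 control features. For 8 arrays the deposited intensity reached the scanner's ceiling of 65535 and showed no sign of normalization. The file of Col0 replicate 1 is different. Its values run from a floor of 340, shared by 7457 probes, to 72360, it has no values for the control features, and above the floor its values are the table's values, taken back from log2, times 1.2 (range 1.198 to 1.202 over 20280 probes). The authors' table holds log2 values of the same 9 arrays, as deposited. Each column's median is 8.61 to 2 decimals, except 8.16 for Col0 replicate 3, and the normalization behind the table is not given in the sources used here. Between 24.6% and 53.9% of a column's probes sit at the column's lowest value.

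Intensities were taken as deposited, put on the log2 scale and quantile-normalized between arrays with limma 3.58.1 in R 4.3.3, with control features left out. The array's own background was taken as the 95th percentile of 50 negative control features (sequences of bacteria and phages). A probe was tested if it lay above this threshold on all arrays of at least 1 group. Col0 replicate 1 has no control values, so Col0 was judged on replicates 2 and 3. This left 5592 tested probes, of which 1493 were above the threshold in Col0, 3238 in P57 and 4152 in P26. The number of arrays, 3 per group, limits the precision. On the 8 arrays with controls, the median probe was 0.99 to 1.15 times the median negative control, and 5.9% to 35.2% of probes lay above the threshold. A raw signal that includes background makes fold changes smaller than those of the transcript.

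A group-means model was fitted over all 9 arrays (lmFit, contrasts.fit and eBayes with default settings), and probes with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were P57 against Col0, P26 against Col0 and P57 against P26, and the probes called in both lines were counted. All p-values are two-sided. Where a probe was above background on no judged array of the dimmer group, the fold is a bound. It sets the brighter group's mean against the mean, per array, of the lowest normalized signal among probes above background or the probe's own signal if higher; on Col0 replicate 1 it is the probe's own signal. The fit and the calls were tested on simulated data with independent probes, each with the same spread in all groups, estimated from the real probes. Normalization, the background filter and the bound on the fold were not run there. The real groups differed in spread (root mean variance 0.57 log2 units in Col0, 0.38 in P57 and 0.27 in P26), so the shares below may not hold for them. For P57 against Col0 over 5592 probes, 34% of 50 probes raised by 1 log2 unit and 98% of 50 raised by 2 were called, as were 58% and 96% of those lowered by 1 and by 2. In the same simulation 4 unchanged probes were called for P57 against Col0, and 2 for P26 against Col0, where no probe had been changed.

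The files used here do not pair the probes with genes. The level of AtPrx71, the gene list tests, the cell type markers and the average over probes of 1 gene were therefore not analysed here, although they had been fixed before the data were examined. Probes are given by their ID and sequence. The rule for named items, also fixed before the data were examined, was the 10 highest and 10 lowest log2 fold changes among called probes with groups that did not overlap, filled to 5 per direction by the smallest p. Because no gene name could be attached, only the first 2 IDs per direction of the P57 comparison are printed, and the rest are summarised.

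The replicate numbers in the labels were checked for pairing by the correlation, across tested probes, of same-numbered arrays' deviations from their group means. For P57 with P26 it was 0.61, 0.26 and 0.60 for numbers 1, 2 and 3, so those numbers were treated as pairs in an additional fit. The differently numbered P57 replicate 3 and P26 replicate 2 had 0.53, above the value of number 2. The numbers of Col0 did not pair with either line, with correlations from -0.38 to 0.06.

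Alternatives set before the data were examined were normexp background correction (offset 50, negative controls), scaling to the 75th percentile, cyclic loess, no filter and a stricter filter, the authors' table, the replicate number as a block, fits of the compared groups alone, eBayes with trend and robust options, array weights, a 2-fold minimum, a floor of 50 intensity units and leaving out each array. Those added after the data were seen were leaving out probes with a run of 4 G, removing from each array its trend with probe length, base counts and longest run of G, a background threshold without control features holding such a run, leaving out Col0 replicates 2 and 3 together, and the block fits of P57 and P26 alone. Figures were drawn with matplotlib 3.10.9, and exact permutation tests were run in Python 3.11.15.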

Results

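Transcript levels in leaves were compared between wild-type Col0 plants and 2 transgenic Arabidopsis lines, P57 and P26, which overexpress the class III peroxidase AtPrx71 per the series text. Class III peroxidases are secreted haem enzymes that use hydrogen peroxide to oxidise substrates in the cell wall. Each group had 3 arrays. The raw median intensity of the 8 unprocessed arrays lay between 950 and 2960 units, and the 95th percentile of the negative control features lay between 1053 and 3829 units. Between 1630 and 9782 of the 27763 Arabidopsis probes on these arrays exceeded it. The probes carry no gene names here, so AtPrx71 itself and pathways were not analysed here and values are given by probe.

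The first question was which transcripts differ in P57 leaves. Of 5592 tested probes, 5 were higher in P57 than in Col0 and 0 were lower (limma, adjusted p under 0.05), with fitted log2 differences from 1.57 to 2.22. The calls depended on the setting. The count was 0 with 75th percentile scaling, with cyclic loess and in a fit of only the groups compared, 1 with trend and robust options or with the stricter filter, and 3 with normexp background correction, in the authors' table or with no filter. Array weights gave 1248, 401 higher and 847 lower, and 642 of the lower ones held a run of 4 G. The probe with the highest fitted difference on the uncorrected intensities was Ath_20_2959, sequence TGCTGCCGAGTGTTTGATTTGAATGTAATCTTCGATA. Probes not above background in Col0 have only a bound, so they cannot be ranked against it. The log2 intensity of Ath_20_2959 was 13.47 ± 0.39 (SD, n = 3) in P57 and 11.25 ± 0.06 (SD, n = 3) in Col0. The difference was 2.22 ± 0.27 (SE, limma adjusted p = 0.0175), or 4.65-fold. This probe was above background on 1 of the 2 Col0 arrays that could be judged. Probe Ath_20_9141, sequence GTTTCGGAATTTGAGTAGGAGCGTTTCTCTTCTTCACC, had 12.83 ± 0.26 in P57 and 10.71 ± 0.08 in Col0 (SD, n = 3 each; limma adjusted p = 0.00508). It was not above background on the judged Col0 arrays, and was at least 3.35-fold higher in P57. For both probes, all 3 P57 arrays lay above all 3 Col0 arrays, which the rule for named probes required. Groups did not overlap for 14.1% of tested probes in this comparison. In the authors' table the difference of Ath_20_2959 was 2.87 log2 units, and that of Ath_20_9141 was larger, at 3.34.

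No probe passed as lower in P57 with the main settings. The 2 lower probes with the smallest p, Ath_20_4108 (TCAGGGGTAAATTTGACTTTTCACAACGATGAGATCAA) and Ath_20_1091 (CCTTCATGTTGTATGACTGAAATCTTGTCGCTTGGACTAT), missed the threshold. Ath_20_4108 had 10.95 ± 0.34 in P57 and 12.28 ± 0.29 in Col0, a difference of -1.33 ± 0.24 (SE; limma adjusted p = 0.0862). It holds a run of 4 G, and its difference was -0.32 (limma adjusted p = 0.7, range over the alternatives 0.000533 to 0.7) with probe composition corrected. Ath_20_1091 had 10.71 ± 0.55 in P57 and 12.36 ± 0.36 in Col0, a difference of -1.65 ± 0.30 (SE; limma adjusted p = 0.0862). It passed with GGGG probes left out (limma adjusted p = 0.0433) and with composition also corrected (-1.72, limma adjusted p = 0.00857), and over the alternatives its adjusted p ran from 0.000896 to 0.51. At an unadjusted p under 0.05 there were 864 probes, 330 higher and 534 lower, where a share of 0.05 gives 280. The spread shared by the groups lay below that of Col0 alone, so no change could give more than 280. With 75th percentile scaling 265 probes had such a p, 68 higher and 197 lower. With cyclic loess it was 592, 265 higher and 327 lower. Of the 534 lower probes, 436 held a run of 4 G, although only 724 of the 5592 tested probes (12.9%) held one. Over all 27763 Arabidopsis probes the share was 2.9%. Col0 was judged on replicates 2 and 3, where probes with the run were raised. The filter can therefore let in probes because they are high in Col0, and the number of lower ones may partly follow from it. The root mean variance within Col0 was 0.57 log2 units over all tested probes and 0.45 over those without the run. With the probes holding the run left out, 13 probes were higher and 1 lower, and all 5 probes called with every probe in the fit were called again. Their own values are the same in both fits, so this is no separate check of them. Leaving out Col0 replicate 1 raised the count to 901, of which 726 were lower and 655 of these held the run, whereas leaving out Col0 replicate 2 or P57 replicate 2 left 0 calls. It was 3 without Col0 replicate 3, P57 replicate 1 or P57 replicate 3, 2 without P26 replicate 2 and 1 without P26 replicate 3.

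**Figure D1:**
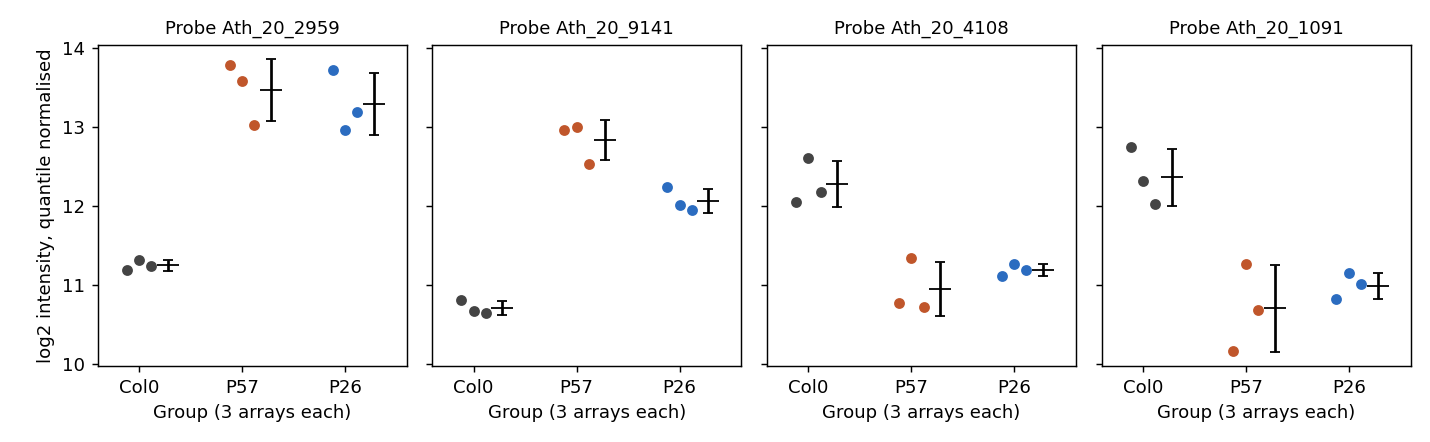
Quantile-normalised log2 intensity of 4 probes on each array (points) by group, with the group mean and SD (bars, n = 3). Ath_20_2959 and Ath_20_9141 passed the test as higher in both lines, and Ath_20_4108 and Ath_20_1091 did not pass as lower in either with the main settings.

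For the second line, P26, 9 probes were higher than in Col0 and 0 were lower, with fitted log2 differences from 1.36 to 2.04. The count was 0 with 75th percentile scaling, cyclic loess, only the groups compared, trend and robust options or the stricter filter, and 5 with no filter. Array weights gave 2658, 1117 higher and 1541 lower, and 667 of the lower ones held a run of 4 G. Ath_20_2959 again had the highest fitted difference on the uncorrected intensities, but some called probes have only a bound against Col0. In the authors' table its difference was 2.72 log2 units, and another called probe reached 3.44. The log2 intensity of Ath_20_2959 was 13.29 ± 0.39 (SD, n = 3) in P26, 2.04 ± 0.27 (SE) above Col0 (limma adjusted p = 0.0261), or 4.11-fold. Ath_20_9141 had 12.07 ± 0.15 (SD, n = 3) in P26 and was at least 1.98-fold higher than in Col0 (limma adjusted p = 0.0419). All 3 P26 arrays lay above all 3 Col0 arrays for both probes. Groups did not overlap for 12.6% of tested probes in this comparison. Among the lower values, Ath_20_1091 was at 10.99 ± 0.17 in P26, a difference of -1.37 ± 0.30 (SE; limma adjusted p = 0.221). It passed with composition corrected and GGGG probes left out (-1.49, limma adjusted p = 0.0217; range over the alternatives 3.02e-05 to 0.862). Ath_20_4108 was at 11.19 ± 0.08, a difference of -1.09 ± 0.24 (SE; limma adjusted p = 0.221). This probe, which holds a run of 4 G, was at -0.21 (limma adjusted p = 0.893, range over the alternatives 1.79e-05 to 0.893) with probe composition corrected. At an unadjusted p under 0.05 there were 619 probes, 245 higher and 374 lower, and 302 of the lower ones held a run of 4 G. Here too the filter can let in such probes through Col0 replicates 2 and 3. With 75th percentile scaling there were 213, 68 higher and 145 lower, and with cyclic loess 428, 199 higher and 229 lower. With probes holding the run left out, 14 were higher and 0 lower, among them all 9 of the calls above, whose own values this does not change. The count was 903 without Col0 replicate 1, and 0 without any one of Col0 replicate 2, Col0 replicate 3, P57 replicate 2 or a P26 replicate. It was 3 without P57 replicate 3.

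Both lines were then compared for the probes they share. Of 10 probes called in either line, 4 were called in both, all higher; Ath_20_2959 and Ath_20_9141 were among them. Independent lists of these sizes would share 0.008 probes. Simulated unchanged groups set against the same controls shared 0.03 on average and at most 1 in 100 draws. Groups without change give few calls, so this count cannot show how many probes lists of these sizes would share through common controls. The shared count was 0 with 75th percentile scaling, cyclic loess, only the groups compared, trend and robust options or the stricter filter, and 1090 with array weights. Without Col0 replicate 1 the lines shared 759 probes, without P57 replicate 3 they shared 1, and without any one of Col0 replicate 2, Col0 replicate 3, P57 replicate 2 or a P26 replicate they shared 0. The 5 probes called in P26 alone were also higher in P57 by their point estimate, and the 1 called in P57 alone was higher in P26. Both comparisons use the same 3 Col0 arrays, so a shared sign can arise with no change in the other line. Across the 5592 probes, which are not independent replicates, the log2 differences of the lines correlated with r = 0.80, against a mean of 0.75 in the simulated groups. The covariance was 0.211 against a simulated mean of 0.108. Without the probes holding a run of 4 G, r was 0.59 against 0.64 simulated, and the covariance was 0.081 against 0.066. The simulation takes P57 and P26 arrays as independent. It also draws each probe independently, so trends common to many probes of an array could widen the real range. The common deviations of their same-numbered arrays add an estimated 0.017 over all tested probes and 0.019 without the run, which brings the values expected with no change to 0.126 and 0.085. The 3 control arrays are too few to give each line at least 2 of its own, so part of the overlap beyond that of independent lists may come from the shared controls.

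The difference between the lines themselves was tested directly. No probe passed for P57 against P26 (limma, 0 of 5592, lowest adjusted p = 0.863). At an unadjusted p under 0.05 there were 168 probes, where a share of 0.05 gives 280. The shared spread includes Col0 (root mean variance 0.57 log2 units, against 0.38 in P57 and 0.27 in P26). It lay above that of the 2 lines, so no change could give fewer than 280. The low count therefore does not show that the lines are alike. Among the 10 probes called against Col0, the lowest limma adjusted p of P57 against P26 was 0.863. Ath_20_9141 was 0.76 ± 0.21 (SE) log2 units higher in P57 than in P26, and its adjusted p was 0.863. Array weights called 24 probes, this one among them (0.84, limma adjusted p = 0.0225; range over the alternatives 0.0225 to 1). Same-numbered arrays of the lines deviated together (r = 0.61, 0.26 and 0.60 across probes), but so did P57 replicate 3 and P26 replicate 2 (0.53). With the replicate number as a block in a fit of these 6 arrays alone, 17 probes passed, 4 higher and 13 lower in P57, by 0.97 to 1.43 log2 units, and 1292 had an unadjusted p under 0.05. None of the 17 was among the 10 probes called against Col0. With the trend in probe base composition removed and probes with a run of 4 G left out, the blocked fit called 0 (lowest adjusted p = 0.144, with 871 at an unadjusted p under 0.05).

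The agreement between arrays varied by group. Over the tested probes, Pearson's r across probes was 0.12 between Col0 replicates 1 and 3, 0.67 between Col0 replicates 1 and 2, and 0.72 between Col0 replicates 2 and 3. It was 0.70 to 0.90 within P57 and 0.85 to 0.98 within P26. Col0 replicate 1 correlated with the P26 arrays at 0.80 to 0.90. The root mean variance of a probe within a group was 0.57 log2 units in Col0, 0.38 in P57 and 0.27 in P26. Without probes holding a run of 4 G and with base composition corrected, r between Col0 replicates 1 and 3 was 0.60.

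**Figure D2:**
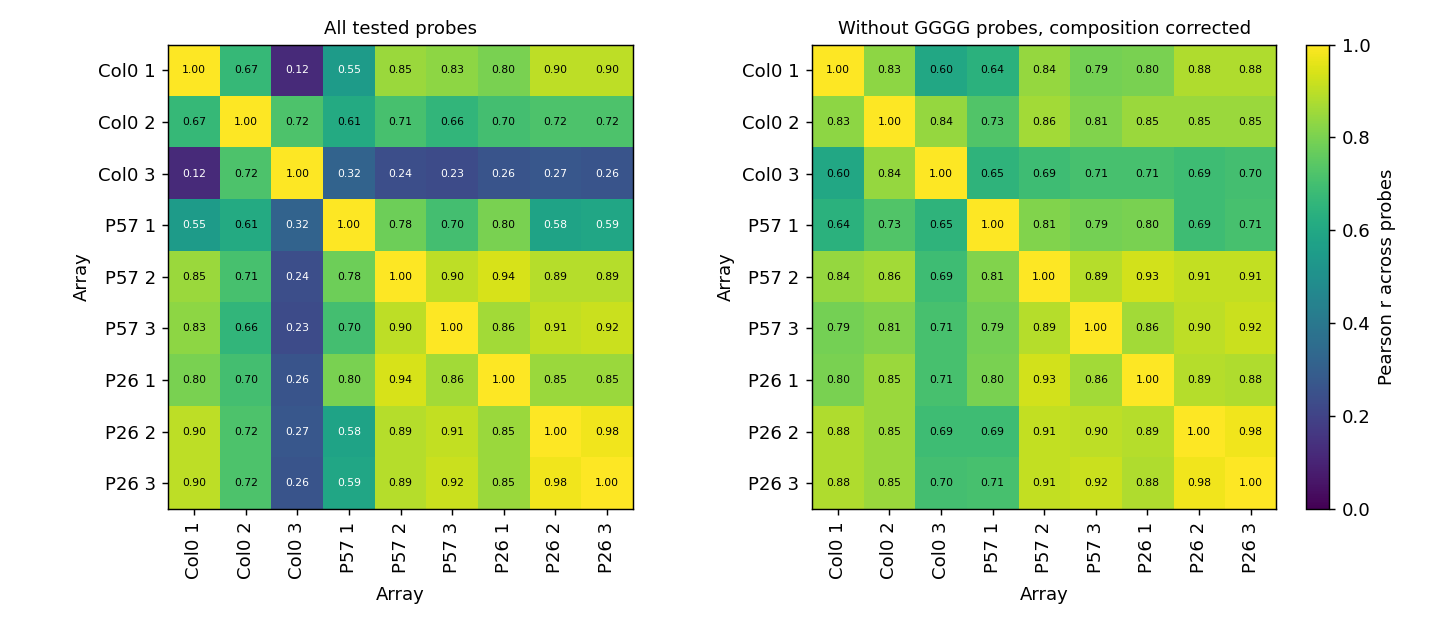
Pearson's r across tested probes for each pair of the 9 arrays, with all tested probes (left) and without GGGG probes after correction for base composition (right). Col0 replicate 3 correlates with Col0 replicate 1 at 0.12 on the left and 0.60 on the right.

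The 810 Arabidopsis probes with a run of 4 G stood apart on Col0 arrays. Relative to the mean of the other arrays, their median signal was 1.69 log2 units higher on Col0 replicate 3 and 0.77 higher on Col0 replicate 2. It was -0.48 on Col0 replicate 1 and between -0.49 and -0.24 on the 6 transgenic arrays. For these arrays the mean of the others includes the raised Col0 replicates 2 and 3, which lowers the values. Probes without the run had medians between -0.03 and 0.03 on every array. Quantile normalization keeps most probes near 0, and only 2.9% of all Arabidopsis probes held the run, so these medians are no separate result. Of the probes with the run 89.4% entered the test, against 18.1% of the others.

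**Figure D3:**
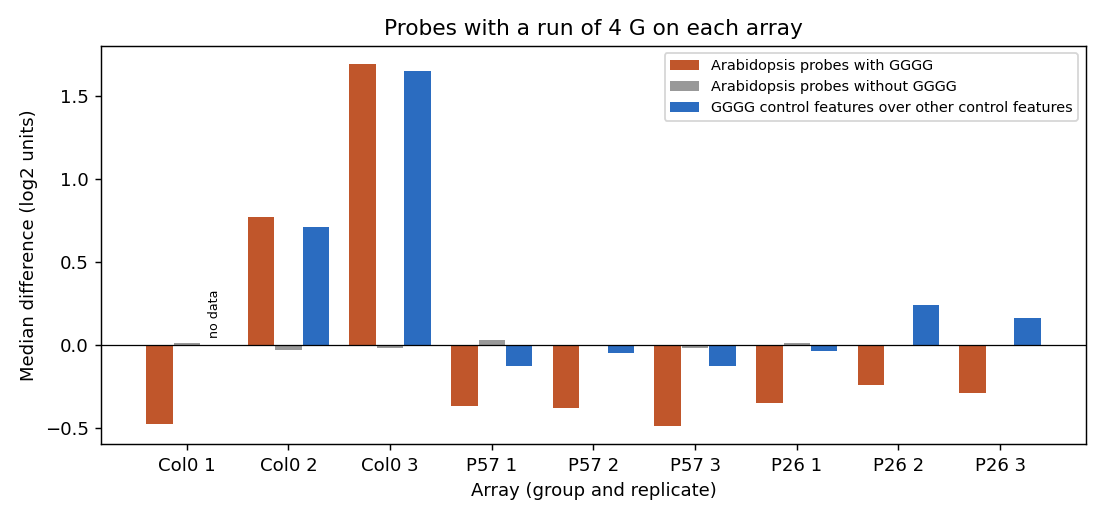
Median log2 difference on each array of Arabidopsis probes with and without GGGG from the mean of the other arrays, and of 5 control features with GGGG from the control features without it on the same array. Bars start at 0, Col0 replicate 1 has no control values, and both kinds of GGGG features are highest on Col0 replicate 3 (1.69 and 1.65).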

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

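Apart from the counts over other splits of the samples, the tests in this part were chosen after the result was seen. On Col0 arrays a signal appeared in control features, which are not tested themselves, although the negative controls among them set the background threshold. That threshold on Col0 replicate 3 was 3398 with them and 2237 without those holding GGGG, and 6100 probes in place of 5592 would be tested without them. The 5 control features with GGGG, made for other organisms, had a median 1.65 log2 units above the other control features of Col0 replicate 3 and 0.71 above those of Col0 replicate 2, against -0.13 to 0.24 on the 6 transgenic arrays.

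The first pattern is that the Col0 arrays lie far apart. Set against the transgenic arrays, the 5 GGGG control features rose on Col0 replicate 3 by a median of 1.67 log2 units (1.41 to 2.29), and all 5 lay above each of 93 control features without the run, whose highest value was 0.59. These features target no plant transcript, so different transcripts in the Col0 leaves are argued against for this part, and binding of label or RNA to runs of G is a candidate explanation. Earlier processing of the Col0 replicate 1 file is argued against as the only source, since in the authors' table, where every array was processed, its r with Col0 replicate 3 is 0.02. That r includes the GGGG probes, and in the main values leaving them out raised r from 0.12 to 0.49. It was not computed without them in the authors' table, so a part played by processing in the other probes stays open. For probes without the run, r after composition correction was 0.60, below the lowest pair of transgenic arrays at 0.69, so different transcripts in these leaves stay open there and cannot be told apart from other technical differences.

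The second pattern is that the fold changes of P57 and P26 correlate. Without GGGG probes the covariance was 0.081, above the highest of 100 simulated unchanged groups at 0.07, but not above 0.085, the simulated mean plus what same-numbered P57 and P26 arrays add by deviating together. The correlation r was 0.59, below the simulated maximum of 0.66. The simulated probes vary independently, so trends common to many probes of an array could widen both simulated ranges. The shared controls with no effect in either line therefore cannot be excluded. Whether GGGG probes alone could carry the correlation also stays open, since with composition corrected the covariance was 0.079 against 0.058 while r was 0.65, equal to the simulated mean. A shared effect of the transgene, or of the lines' common background, is untested.

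The third pattern is that arrays differ by the G content of the probe. Among probes without GGGG, the correlation across probes of an array's deviation with the number of G ran from -0.45 to 0.37, and all 3 groups held both signs, which argues against the line as its source. Over the 8 arrays with controls, this value and the log2 median of the negative controls had Spearman's rho 0.71 (exact permutation p = 0.0576, adjusted over the 2 coefficients 0.0782) and Pearson's r 0.66 (exact permutation p = 0.0782, adjusted 0.0782). Without the 2 arrays farthest from the median background, P26 replicate 2 and P57 replicate 1, r was 0.44 (exact permutation p = 0.435). The background level may be the source, but 8 arrays do not decide it, and no biological explanation other than the line was tested.

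For the counts of calls, each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. For P57 against Col0 the real split gave 5 calls and the highest other 0, so 1 split reached the real count. For P26 against Col0 the real split gave 9, the highest other 0, and again 1 split reached it. For P57 against P26 all 10 splits gave 0.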

How the results depend on the processing

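The alternatives with GGGG probes left out, with composition correction, with the other background threshold, without Col0 replicates 2 and 3 together and with P57 and P26 alone in a block fit were chosen after the data were seen. Counts are given in the order P57 against Col0 (5 probes with the main settings), P26 against Col0 (9) and both lines (4), and the cause of a moved count was not tested unless the setting itself shows it. All 3 counts fell to 0 with 75th percentile scaling, with cyclic loess and in fits of only the groups compared. Such fits have fewer arrays behind the spread and lose the lower spread of the other line (root mean variance 0.57 log2 units in Col0, 0.38 in P57 and 0.27 in P26). The main fit therefore rests on a spread below that of Col0. Without Col0 replicates 2 and 3 together, the lone Col0 array is assumed to vary like the other groups. There Ath_20_2959 was 2.33 log2 units higher in P57 and 2.13 in P26. Both values rest on Col0 replicate 1 alone, the array with already processed values. They give a size only and cannot show whether the difference holds. The 3 counts were 1, 0 and 0 with trend and robust options, and also among the 639 probes above background on every array with controls. Without a filter on dim probes the first 2 counts were 3 and 5. The count for P57 was 3 with normexp background correction and 3 in the authors' table. Array weights gave 1248 (847 lower), 2658 (1541 lower) and 1090, and 24 for P57 against P26, where Ath_20_9141 passed at 0.84; they gave Col0 replicate 2 a weight of 4.15 and the other Col0 arrays 0.24 and 0.23. GGGG probes left out gave 14, 14 and 9, composition correction 24, 18 and 11, both together 28, 18 and 12, and the authors' table with both gave 24, 18 and 12. Leaving out 1 array at a time gave 0 to 901, 0 to 903 and 0 to 759; the highest values are those without Col0 replicate 1. The 2-fold minimum, the floor of 50 (below every signal, so it moved nothing) and the threshold without GGGG controls left all 3 counts unchanged. The 2-fold minimum could not lower them, since the lowest called difference was 1.36 log2 units. P57 against P26 stayed at 0 in 27 of 29 alternatives.

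The replicate block over all 9 arrays gave 1, 0 and 0, and 0 for P57 against P26. For Col0, same-numbered arrays do not pair with either line (correlations of deviations from -0.38 to 0.06), so they share only a number. In P57 and P26 alone the block gave 17 calls, against 0 with composition correction and GGGG probes left out.

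Ath_20_2959 kept its direction against Col0 in all 25 alternatives for each line, with log2 differences of 1.76 to 3.13 in P57 and 1.76 to 2.92 in P26, and fell short of the threshold in 10 and 12 of them (adjusted p up to 0.406 and 0.281). Ath_20_9141, for which Col0 gives only a bound, kept its direction and fell short of the threshold in 6 and 13 (adjusted p up to 0.406 and 0.862). Ath_20_1091 ran from -2.75 to -1.34 in P57 and -2.29 to -1.11 in P26 and passed in 6 and 5 of 25. Ath_20_4108 ran from -2.25 to -0.32 and from -1.73 to -0.21 over 22 and passed in 2 and 2; the values nearest 0 are those with probe composition corrected. For P57 against P26, Ath_20_2959 reversed to -0.19 with 75th percentile scaling, neither value past the threshold. Scaling to the 75th percentile moved the median log2 difference of all tested probes from 0.08 to -0.10 for P57 and from 0.06 to -0.04 for P26. The brightest probe per gene, slide batches, gene lists and AtPrx71 were not run, since the files used here hold no gene names or slides. How far signal over background limits the counts was not tested beyond the normexp setting; the median probe was 0.99 to 1.15 times the median negative control.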

Other observations

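These observations rest on settings chosen after the data were seen. With base composition corrected and GGGG probes left out, limma called 23 probes higher and 5 lower in P57 against Col0, with fitted log2 differences of 0.92 to 2.18 and of -1.89 to -1.02. In P26 it called 17 higher, by 1.03 to 1.99, and 1 lower. All 5 P57 calls and all 9 P26 calls of the main settings were among them. Both lines shared 11 higher probes and 1 lower, where independent lists would share 0.08 and 0.001. Both comparisons use the same 3 Col0 arrays, so the lists are not independent. Simulated unchanged groups shared at most 1, but they give few calls. Sharing through the common controls therefore cannot be told apart from a shared change. The shared lower probe was Ath_20_1091, at -1.72 ± 0.24 (SE; limma adjusted p = 0.00857) in P57 and -1.49 ± 0.24 (SE; limma adjusted p = 0.0217) in P26, with the 3 arrays of each line below all 3 Col0 arrays. Over all alternatives its adjusted p ran from 0.000896 to 0.51 in P57 and from 3.02e-05 to 0.862 in P26.

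Over the 27440 Arabidopsis probes with a value on all 9 arrays, with no filter on dim probes, groups did not overlap for 10% of probes in P57 against Col0 (1394 higher, 1339 lower), 6.9% in P26 against Col0 (1038 and 854) and 8.3% in P57 against P26 (1003 and 1274). Chance gives 10%. Among the 5592 tested probes the shares were 14.1%, 12.6% and 14.3%, but the filter takes probes by their signal within a group, so 10% is not the share that no change would give there.

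In the fit of P57 and P26 alone with the replicate number as a block, the real assignment called 17 probes. The 3 other splits that part every same-numbered pair called 0 each, and 4 such splits are too few for a share under 0.05.

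Without Col0 replicate 1, 90.2% of the probes called lower in P57 and 89.8% of those called lower in P26 held GGGG. The Col0 arrays left are those where such probes were raised and on which the filter judged Col0. All probes called with the main settings were again among the calls.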
